A study of Mus musculus with 33 samples.

How the data were processed

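Total RNA from mouse cells was measured on Illumina bead arrays. Per the labels' protocols, cells grew in a monolayer on gelatin, with or without irradiated fibroblast feeders, in embryonic stem cell medium with fetal bovine serum or a serum replacement, RNA was extracted with Trizol and biotinylated cRNA was made with an Ambion kit. Which cultures had feeders or which serum is not given in the sources used here. The labels put 33 arrays in 11 groups of 3, and the replicate number was taken from each title. The labels do not say that replicates were separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

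The RepSox iPS arrays were made on a platform of their own with 24613 probes. The other 30 arrays, in 10 groups, shared a platform with 25697 probes. Platform and cell type cannot be told apart for the iPS cells, so their values were set beside the others with no test.

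The authors deposited a scanner table for each platform that gives each probe's intensity on a linear scale, with negative values after background subtraction, and a detection p-value. BeadStudio is the only program named in the submitters' processing notes, and its version is not given in the sources used here. The authors also deposited a series matrix of processed intensity on a linear scale for the same arrays. Its column medians were 10.7 for each of the 30 arrays and 17.6 for each iPS array. The ranks of 31 of its columns matched the scanner column of the same title (Spearman's rho of 1). The columns of replicate 3 of the untreated and the RepSox-treated OKMS6 cells at 48 h each matched the other's scanner column (rho of 1) and not their own (rho of 0.931). The method that made the series matrix from the scanner values, and whether it centred any gene, stays unknown. Scanner values under the scanner table's names gave the reported results, and the series matrix served as an alternative.

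Values were processed with limma 3.58.1 in R 4.3.3. Background was corrected and arrays were quantile normalized with neqc, with an offset of 16 and the background inferred from the detection p-values, because no control probes were in the table used here. Values are log2 intensities. Probes with a detection p under 0.05 on at least 3 of the 30 arrays were kept, 15635 in all, of which 14698 had a gene name. The probe with the highest mean stood for a gene, which left 10614 genes. It was chosen anew where an alternative changed the values or the arrays. Names came from GEO's platform annotation, in which 23978 probes of the larger platform had 1 gene symbol and 1719 were unlisted. On the iPS platform 20984 probes had 1 symbol, 1 had several and 3628 were unlisted. Entrez identifiers of 23962 probes of the larger platform were found in a RefSeq gene table, and 0 symbols needed an update.

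A linear model with a mean for each of the 10 groups (20 residual degrees of freedom, 3.46 prior) was fitted with lmFit and eBayes, and p-values are two-sided and adjusted by the Benjamini-Hochberg method. A gene counted as changed at an adjusted p under 0.05. RepSox-treated OKMS6 cells were compared with untreated cells at each time, and fibroblasts after 1 week with RepSox with untreated fibroblasts, for which the labels give no time. The embryonic stem cell lines, fibroblasts and untreated OKMS6 cells were compared with each other as means of group means. A moderated F test asked whether the RepSox effect or the untreated OKMS6 cells differed between times, and a contrast of contrasts asked whether the effect differed between fibroblasts and OKMS6 cells. Changes are given on the log2 scale with their standard errors (SE), and levels as mean ± SD. Where a gene was detected on no array of the dimmer group, its fold is a lower bound. The bound sets the brighter group's mean against the higher of the dim probe's signal and the lowest detected signal on each array.

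A set of 27 gene lists with 352 entries covered pluripotency, TGF-beta, Nodal and BMP targets, matrix, contractile, fibroblast, epithelial and other lineage markers, Myc and its targets, cell cycle, p53, interferon, stress and metabolism. Of the entries, 314 were in the platform's annotation. The lists, tests, alternatives and rule for named genes were chosen before the data were examined. Each list with at least 3 measured genes was tested by camera against all other genes, with a preset correlation between genes of 0.01 and adjustment over the lists of a comparison. Member counts are also given adjusted over the list alone. The Myc family had 2 measured members and was not tested as a list. The 200 genes with the largest rise and the 200 with the largest fall from fibroblasts to embryonic stem cells served as a further pair of lists in the OKMS6 comparisons.

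Genes named were the 10 largest rises and falls of a comparison with no overlap between arrays (without clone or provisional names), up to 4 members of each list with the smallest adjusted p and members that went against it, and a fixed set: Nanog, Pou5f1, Sox2, Klf4, Myc, Mycl, Mycn, Id1, Id2, Id3, Smad7, Lefty1, Lefty2, Zfp42 and Thy1. Smad7 was not analysed here, Mycn did not pass the detection filter, and another gene of the set is not reported here.

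For the iPS cells, 9495 genes were matched by symbol and all arrays were quantile normalized together over them. Genes at least 4-fold apart between embryonic stem cells and fibroblasts were counted as nearer one or the other.

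The procedure was tested on simulated data built from the OKMS6 comparison at 48 h, with 200 of 10614 genes changed in each of 10 runs. The changed genes were drawn from those above the median signal, and all groups had the same spread, unlike the data. It recovered 11.3% of changes of 0.5 log2, 61.6% of changes of 1 and 92.7% of changes of 2, and 6.32% of calls were unchanged genes. The shifted list, with every member raised by 1 log2 and noise independent between genes, was called in 10 of 10 runs. This does not show how lists with smaller shifts or correlated members fare. In a separate check with no change built in, which skipped background correction and normalization, 0 genes were called. A first single run had missed its criterion, and the runs were then pooled.

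Same-numbered arrays of compared groups were checked for shared deviations. In the OKMS6 comparison at 48 h every pair's correlation across genes exceeded 0.1, which no other comparison reached. The values were 0.225, 0.102 and 0.338 for replicates 1, 2 and 3. Replicate numbers may thus pair the arrays there, but the reported fit holds no pairing in any comparison. At 48 h it called 1695 genes, and 1592 with the replicate number as a block, an alternative applied to every comparison. Alternatives were no background correction, median scaling, the series matrix, other detection filters, all probes, another variance model, array weights, only the groups compared, the replicate number as a block, a 2-fold minimum, other list tests and each array left out. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Mean signal per array ran from 66.6 to 429, and 28.7% to 52.8% of probes were detected. The number of arrays limits the precision.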

Results

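RNA levels were measured in mouse embryonic stem cells (lines R1 and V6.5), mouse embryonic fibroblasts, fibroblasts after 1 week with RepSox, the OKMS6 line with or without RepSox at 10, 24 and 48 h, and an induced pluripotent stem (iPS) line. RepSox inhibits the kinase of the TGF-beta type I receptor. OKMS6 is a partially reprogrammed line made from virally transduced fibroblasts, and the labels name viral Sox2 for it. The iPS line was made with RepSox in place of viral Sox2. Each of the 11 groups had 3 arrays. Within groups other than V6.5, arrays correlated at 0.979 to 0.997 across probes. V6.5 replicates 1 and 3 were dim, with mean signals of 66.6 and 79.5 against 329 for replicate 2, and 31.4% and 28.7% of probes detected against 47.3%. Their correlations with replicate 2 across probes were 0.820 and 0.783. The comparisons ask how RepSox changed OKMS6 cells and fibroblasts over time, and how the iPS line stood to embryonic stem cells and fibroblasts.

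At 10 h, RepSox raised Tfap2c, Gadd45g and Edn2 in OKMS6 cells and lowered the list of cell stress genes. Tfap2c, which encodes a transcription factor of trophectoderm and germ cells, rose by 2.00 ± 0.11 on the log2 scale (SE, 3 against 3 arrays, adjusted p = 1.5e-11), and Gadd45g, a growth arrest and DNA damage response gene, by 2.07 ± 0.14. Edn2, a vasoconstrictor peptide, was detected on no untreated array and was at least 3.45-fold higher with RepSox. Cdh1, which encodes the epithelial adhesion protein E-cadherin, rose by 1.16 ± 0.19. Genes that fell included Pecam1, an endothelial adhesion molecule (-2.25 ± 0.33), Sfn (-1.88 ± 0.39), Chac1, a glutathione-degrading enzyme of the unfolded protein response (-1.86 ± 0.36), and the keratin Krt14 (-1.56 ± 0.25). Of 10614 genes, 412 changed, 269 up and 143 down, and 73 of them by at least 2-fold.

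Among the fixed lists at 10 h, cell stress genes were lower as a group (2 of 9 fell, 3 adjusted over the list alone, adjusted p = 5.3e-04). Myc target genes were lower as a group (adjusted p = 0.0070), although 0 of 14 changed singly on either adjustment. Srm, which makes spermidine, was at -0.86 ± 0.27 and did not pass (adjusted p = 0.082). The p53 and arrest list was higher (2 of 10 rose, 4 adjusted over the list alone, adjusted p = 0.022), with cyclin G1 gene Ccng1 at 0.51 ± 0.11. The trophectoderm list was higher (adjusted p = 0.035, and adjusted p = 0.24 with an estimated correlation, 0.062 without background correction and 0.078 without V6.5 replicates 1 and 3), and of its 6 measured genes Tfap2c alone rose, on either adjustment. Pluripotency genes were not called as a list (adjusted p = 0.75); 3 of 24 rose, and adjusted over the list alone 3 rose and 1 fell. Nanog was detected on no array of either group. Pou5f1 was at -0.55 and Myc at -0.41, and neither passed (adjusted p = 1.00 and 0.42), although without V6.5 replicates 1 and 3 Pou5f1 did (adjusted p = 0.0090). With median scaling the p53 and trophectoderm calls were lost (adjusted p = 0.27 and 0.18). The count of 412 genes fell to 267, 239 and 229 without replicates 1, 2 and 3 of the untreated cells and to 245 without replicate 3 of the treated cells, and was 256 with median scaling and 218 with the series matrix.

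At 24 h, Igf2 and Tfap2c were among the genes that rose in OKMS6 cells, and the lists of hypoxia and glycolysis, cell stress and Myc target genes fell. Igf2, an imprinted growth factor gene, rose by 4.24 ± 0.14 (adjusted p = 2.4e-16), the interleukin receptor gene Il7r by 2.77 ± 0.12, the neuroendocrine transcription factor gene Insm1 by 2.62 ± 0.11, and Tfap2c by 2.51 ± 0.11. The atypical cadherin gene Cdh13 and the ligand gene Wnt5a were detected on no untreated array and were at least 5.01-fold and 5.24-fold higher. Pecam1 (-3.29 ± 0.33, detected on 1 of 3 treated arrays), the stress-induced Nupr1 (-2.87 ± 0.19), Chac1 (-2.60 ± 0.36) and the integrin gene Itga7 (-2.12 ± 0.18, detected on 2 of 3 treated arrays) fell. The calls covered 974 genes, 603 up and 371 down.

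Hypoxia and glycolysis genes fell as a group at 24 h (5 of 10 fell, 6 adjusted over the list alone, adjusted p = 3.5e-06), with the aldolase gene Aldoa at -1.15 ± 0.18 and the growth factor gene Vegfa at -0.99 ± 0.18. Cell stress genes fell (4 of 9, 6 adjusted over the list alone, adjusted p = 2.5e-04), and so did Myc target genes (4 of 14 on either adjustment, adjusted p = 0.0035), among them Odc1, the first enzyme of polyamine synthesis (-0.76 ± 0.16). The immediate early list did not pass (adjusted p = 0.0502); 3 of its 8 genes fell, 4 adjusted over the list alone, including Egr1, which was detected on no treated array and was at least 1.69-fold lower. Nanog, a homeobox gene of the pluripotency network, was detected on all 3 treated arrays and on no untreated array, at least 1.43-fold higher (adjusted p = 2.9e-05). Of 24 pluripotency genes 6 rose and 1 fell on either adjustment, and the list was not called (adjusted p = 0.11). In the contractile list Acta2, smooth muscle actin, rose by 1.88 ± 0.12 and Mylk, myosin light chain kinase, fell by 1.78. Of 9 BMP targets 4 rose, and adjusted over the list alone 4 rose and 1 fell, and the list was not called (adjusted p = 0.11). Median scaling moved the median of all genes by -0.18 log2 and called 233 genes up and 643 down. Without replicate 2 of the treated cells 629 genes were called, and with the series matrix 614, or 951 with both 48 h arrays numbered 3 left out of it.

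At 48 h, RepSox-treated OKMS6 cells had higher Nanog, Eras and Dppa5a, raised cell cycle genes, and lowered hypoxia and cell stress genes. Nanog rose by 2.85 ± 0.13 (adjusted p = 1.4e-14), from 4.81 ± 0.08 to 7.67 ± 0.09 (SD, n = 3). The embryonic stem cell genes Eras and Dppa5a rose by 2.34 ± 0.11 and 2.13 ± 0.13. The muscle-lineage repressor gene Msc rose by 4.76 ± 0.15 (2 of 3 untreated arrays detected it), Igf2 by 4.15 ± 0.14 and Insm1 by 3.31 ± 0.11. The kininogen gene Kng1, Il7r and the homeobox gene Rhox9 were detected on no untreated array and were at least 19.03-fold, 13.7-fold and 8.85-fold higher. The acute-phase gene Serpina3n fell by 4.40 (SE 0.11), Pecam1 by 3.76 (SE 0.33, detected on 1 of 3 treated arrays) and the ferritin receptor gene Scara5 was at -3.51 ± 0.17. Of the 1695 genes called, 737 rose and 958 fell.

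Cell cycle genes rose as a group at 48 h (7 of 16, 12 adjusted over the list alone, adjusted p = 1.3e-05), with the mitotic kinase gene Aurka at 1.22 ± 0.12 and the survivin gene Birc5 at 1.07 ± 0.18. Hypoxia and glycolysis genes fell (5 of 10 on either adjustment, adjusted p = 5.8e-05), with the oxygen sensor gene Egln3 at -1.99 ± 0.22 and Vegfa at -1.52 ± 0.18. Cell stress genes fell (5 of 9 on either adjustment, adjusted p = 0.0067). TGF-beta target genes fell (4 of 13, 6 adjusted over the list alone, adjusted p = 0.016), with the repressor gene Bhlhe40 at -2.19 ± 0.26. That list was not among the 4 lists called at 10 h or the 3 called at 24 h. BMP target genes were higher (4 of 9 on either adjustment, adjusted p = 0.029, and adjusted p = 0.24 with an estimated correlation), with the helix-loop-helix genes Id2 (detected on 2 of 3 untreated arrays) and Id3 at 2.43 ± 0.26 and 0.99 ± 0.25. Endothelial genes were lower (2 of 4 on either adjustment, adjusted p = 0.033, and adjusted p = 0.071 with an estimated correlation and adjusted p = 0.077 with no detection filter): Pecam1 and the adhesion gene Esam, at -1.69 ± 0.20, fell. Pluripotency genes were higher (6 of 24 rose and 1 fell on either adjustment, adjusted p = 0.035, and adjusted p = 0.22 with an estimated correlation). The gene that fell was Tdgf1, a Nodal co-receptor (-2.73 ± 0.21). Pou5f1 was at -1.10 (SE 0.72) and Klf4 at -0.999 (SE 0.52), with no overlap between the arrays compared, and neither passed (adjusted p = 0.40 and 0.24). Without V6.5 replicates 1 and 3 both passed, at -1.09 and -0.99 (adjusted p = 7.5e-07 and 6.0e-05). Myc fell by 1.09 (SE 0.20, adjusted p = 3.3e-04). Whether the Pou5f1, Klf4 and Myc signals of this virally transduced line come from viral copies or the cells' own genes was not tested. Acta2 rose by 2.14 ± 0.12 while Mylk was detected on no treated array and was at least 4.79-fold lower, and the contractile list was not called (adjusted p = 0.73). The fibroblast list was not called either (adjusted p = 0.93); 1 of 15 fell on either adjustment, Thy1, a fibroblast surface glycoprotein, at -1.27 ± 0.18. With median scaling 347 genes rose and 830 fell, and the pluripotency and TGF-beta calls were lost (adjusted p = 0.092 and 0.070), and the pluripotency and BMP calls without V6.5 replicates 1 and 3 (adjusted p = 0.36 and 0.052). With the series matrix, whose names for both arrays numbered 3 are exchanged against the scanner table, 0 genes were called by limma and 187 had an unadjusted p under 0.05, and the hypoxia, endothelial, BMP, TGF-beta and pluripotency calls were lost (adjusted p = 0.44, 0.28, 0.081, 0.98 and 0.44). With both arrays left out of it, the series matrix called 1136 genes, and the TGF-beta and pluripotency calls were lost (adjusted p = 0.052 for each). The scanner values without both arrays called 1041.

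**Figure D1:**
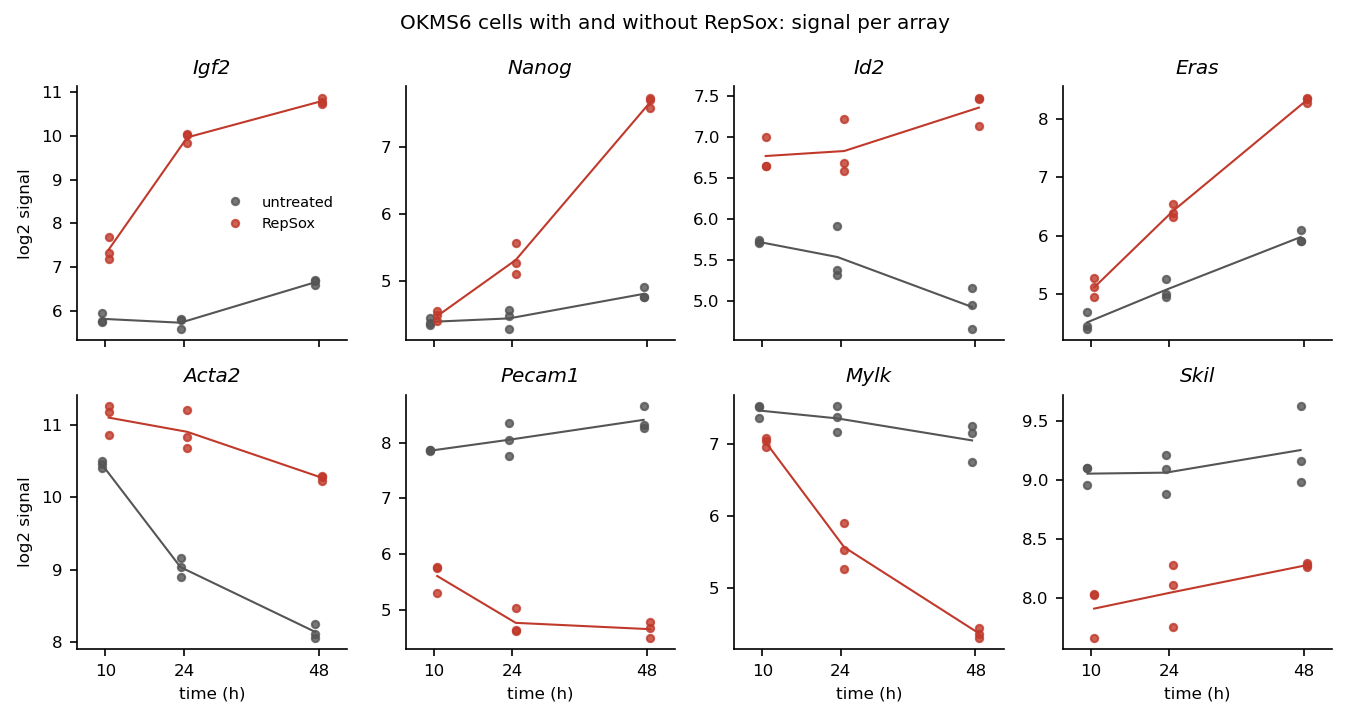
Log2 intensity of selected genes in OKMS6 cells at 10, 24 and 48 h, untreated or with RepSox, with points for single arrays and lines through the means of 3 arrays. Nanog reached 7.67 with RepSox at 48 h against 4.81 untreated, and Pecam1 fell by 3.76 on the log2 scale at that time.

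The RepSox effect changed with time for 934 genes, for 495 with median scaling, 620 with the replicate number as a block, 57 with the series matrix and 2852 with only the groups compared. Of genes called at 10 h and at 24 h, 191 rose at both (15.3 would be shared by independent lists) and 89 fell at both (4.998 by independent lists). Between 24 h and 48 h, 256 rose at both (41.9 by independent lists) and 225 fell at both (33.5). The comparisons share no arrays, but all calls use each gene's spread over the 30 arrays, so independent lists are no exact reference. Between OKMS6 cells at 24 h and fibroblasts even opposite changes exceeded it (112 against 74.3). Between 10 h and 24 h opposite changes were fewer (2 against 17.5), as between 24 h and 48 h (33 against 80.2). These overlaps moved with the processing: with median scaling 88 and 133 rose at both times of each pair, and without V6.5 replicates 1 and 3, 539 and 552. Between 10 h and 48 h, 97 rose at both (18.7 by independent lists), 75 fell at both (12.9) and 35 changed in opposite directions (34.2). At all 3 times 94 genes rose, 64 fell and 14 changed in mixed directions. Acta2, Igf2 and Tfap2c rose and Pecam1, Itga7 and Chac1 fell at each time. In untreated OKMS6 cells 2125 genes differed between the times, 1330 with the series matrix and 5526 with only the groups compared. Genes higher in fibroblasts than in embryonic stem cells were higher with RepSox at 10 h (10 of 200 rose and 1 fell, adjusted p = 5.1e-04, and adjusted p = 0.060 with an estimated correlation). They were higher too at 24 h (27 rose and 7 fell, adjusted p = 0.0058, and adjusted p = 0.14 with an estimated correlation). Genes higher in embryonic stem cells had about as many rises but were not called at 10 h (9 rose and 3 fell, adjusted p = 0.19) or 24 h (27 rose and 13 fell, adjusted p = 0.18). At 48 h genes higher in fibroblasts were not called (18 rose and 34 fell, adjusted p = 0.24). Genes higher in embryonic stem cells were then higher (53 of 200 rose and 31 fell, adjusted p = 0.018, and adjusted p = 0.44 with an estimated correlation). That last call was also lost without V6.5 replicate 2 (adjusted p = 0.099), without replicates 1 and 3 (0.073) and with the series matrix (0.47). The calls for 934 and 2125 genes rest on the spread of all 30 arrays. Without V6.5 replicates 1 and 3, an alternative added after the data were seen, 1333, 2549 and 3450 genes were called at 10, 24 and 48 h, 2779 for the effect between times and 4762 for untreated cells between times.

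Fibroblasts after 1 week with RepSox had higher adipocyte and smooth muscle genes than untreated fibroblasts, and lower Cxcl14, Col1a2 and Skil. The labels give no time for the untreated fibroblasts, so any effect of the week in culture is not separated from that of RepSox. Adiponectin (Adipoq), a hormone of fat cells, was detected on no untreated array and was at least 222-fold higher (adjusted p = 9.8e-21, 3 against 3 arrays). Lipoprotein lipase (Lpl) rose by 4.21 ± 0.16 and Pparg, the nuclear receptor that drives fat cell differentiation, by 2.94 ± 0.15. Smooth muscle myosin (Myh11) rose by 4.30 ± 0.15 and Mylk by 3.22 ± 0.18. The chemokine gene Cxcl14 fell by 4.65 (SE 0.28), the collagen gene Col1a2 by 2.83, and Skil, a SMAD-binding repressor induced by TGF-beta, by 3.22 (SE 0.23). The test called 1608 genes, 780 up and 828 down, and 905 with median scaling, 555 up and 350 down. Without V6.5 replicates 1 and 3, an alternative added after the data were seen, it called 3000, and with array weights 4205.

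Of 6 adipocyte genes, 5 rose on either adjustment (adjusted p = 3.6e-13). Of 13 contractile genes, 7 rose on either adjustment (adjusted p = 1.7e-08), among them Lmod1, leiomodin, at 1.94 ± 0.10. BMP targets rose (6 of 9 on either adjustment, adjusted p = 1.1e-05), with Id4 at 2.04 ± 0.27 and Hey1 at 1.93 ± 0.12. Interferon and inflammation genes rose (5 of 11, and adjusted over the list alone 6 rose and 1 fell, adjusted p = 0.0012), with the chemokine gene Ccl5 at least 12.5-fold higher and Oasl2, detected on 1 of 3 untreated arrays, at 1.34 ± 0.24. Matrix genes were lower as a group (11 of 23 fell and 5 rose, 12 and 6 adjusted over the list alone, adjusted p = 0.027, and adjusted p = 0.28 with an estimated correlation). The protease inhibitor gene Timp1 (-1.87 ± 0.13) and elastin (Eln, -1.64 ± 0.09) fell, whereas the basement membrane collagen gene Col4a1 (1.49 ± 0.23) and decorin (Dcn, 1.01 ± 0.22) rose. Cell stress genes were lower (5 of 9 fell and 1 rose on either adjustment, adjusted p = 0.027, and adjusted p = 0.074 with an estimated correlation), with asparagine synthetase (Asns) at -1.13 ± 0.15 and the chaperone gene Hspa1a rising by 1.08 ± 0.17. Of 13 TGF-beta targets 4 fell and 1, endothelin gene Edn1 (2.07 ± 0.36), rose; adjusted over the list alone 5 fell and 3 rose, and the list was not called (adjusted p = 0.12). Of 15 fibroblast genes 5 rose and 2 fell (6 and 2 adjusted over the list alone), with Prrx1 at 1.13 ± 0.20, and the list was not called (adjusted p = 0.12). Mycl rose by 1.95 ± 0.17, whereas Nanog was detected on no array of either group. The matrix and cell stress calls were lost without treated replicate 1 (adjusted p = 0.11 and 0.079) or 2 (0.13 and 0.057) and with the series matrix (0.078 and 0.10), and the matrix call with the replicate number as a block (0.054).

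The change with RepSox differed between fibroblasts at 1 week and OKMS6 cells at 48 h for 1699 genes, 914 with a higher and 785 with a lower change in fibroblasts. The times differ, and cell type and time cannot be told apart in this comparison. Contractile genes were relatively higher in fibroblasts (7 of 13 higher and 1 lower, 9 and 1 adjusted over the list alone, adjusted p = 8.5e-06), and so were adipocyte genes (5 of 6 higher on either adjustment, adjusted p = 7.4e-10) and hypoxia and glycolysis genes (7 of 10 higher on either adjustment, adjusted p = 1.5e-05). Interferon genes were relatively higher (3 of 11, 5 adjusted over the list alone, adjusted p = 0.017, and adjusted p = 0.069 with an estimated correlation), as were immediate early genes (3 of 8 on either adjustment, adjusted p = 0.018, and adjusted p = 0.066 with an estimated correlation). Cell cycle genes were relatively lower (4 of 16 on either adjustment, adjusted p = 0.0067, and adjusted p = 0.069 with an estimated correlation). Of genes called in both, 85 rose in both (54.2 by independent lists), 210 fell in both (74.7) and 151 changed in opposite directions (128). With median scaling these were 37, 85 and 85, and without V6.5 replicates 1 and 3 they were 249, 488 and 450. Both comparisons use the same spread for each gene, so independent lists are no exact reference here either. The difference was called for 665 genes with the series matrix, 3444 with only the groups compared and 3530 without V6.5 replicates 1 and 3. Median scaling called 792 higher and 352 lower, and with it the cell cycle and immediate early calls were lost (adjusted p = 0.060 and 0.075). With the series matrix as named, the hypoxia, cell cycle and immediate early calls were lost (adjusted p = 0.15, 0.75 and 0.15), but not with both 48 h arrays numbered 3 left out of it.

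**Figure D2:**
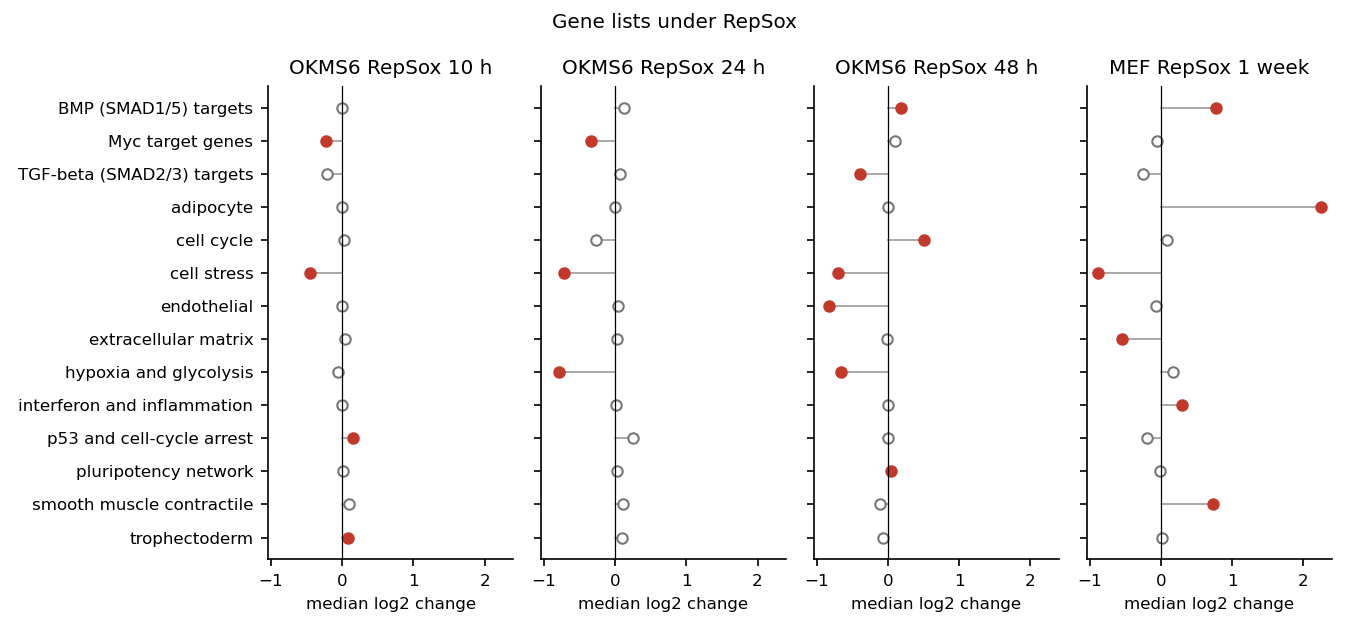
Median log2 change of the fixed gene lists in the 4 RepSox comparisons, a positive value meaning higher with RepSox, with filled marks where camera called the list. The adipocyte list reached 2.25 in fibroblasts, and the cell cycle list 0.51 in OKMS6 cells at 48 h.

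Embryonic stem cells had higher pluripotency and epithelial genes and lower matrix and fibroblast genes than fibroblasts. Dppa5a, Nanog and Esrrb, genes of the pluripotency network, were detected on no fibroblast array and were at least 518-fold, 138-fold and 90.4-fold higher in embryonic stem cells (6 against 3 arrays). All 24 pluripotency genes were higher on either adjustment (adjusted p = 2.3e-16). Of 13 epithelial genes 12 were higher on either adjustment (adjusted p = 4.9e-07), with keratin gene Krt8 at 6.23 ± 0.18. Matrix genes were lower (22 of 23 on either adjustment, adjusted p = 1.1e-13), with the collagen cross-linking enzyme gene Lox at -5.85 ± 0.63 (detected on 4 of 6 embryonic stem cell arrays), and so were all 15 fibroblast genes on either adjustment (adjusted p = 9.9e-08), with Thy1 at -3.94 ± 0.16. Contractile genes were lower (11 of 13, with Des and Csrp1 higher, on either adjustment, adjusted p = 1.2e-05). Cell cycle genes were higher (14 of 16, with 1 lower, on either adjustment, adjusted p = 1.4e-04), with the replication helicase gene Mcm5 at 3.41 ± 0.13. The 1 lower gene was Mcm6 at -0.79, for which 2 of 3 other probes were called in the opposite direction. Nodal targets (4 of 5 higher on either adjustment, adjusted p = 0.029), Myc targets (7 of 14, 0.035) and chromatin regulators (5 of 10 higher and 1 lower, 0.035) were called higher. With an estimated correlation their adjusted p-values were 0.21, 0.055 and 0.13, and the latter pair was lost without V6.5 replicate 2 (adjusted p = 0.12 and 0.083). Of the 6646 genes called, 3386 were higher and 3260 lower.

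The lines R1 and V6.5 differed in 6219 genes, 3081 higher and 3138 lower in R1, but V6.5 replicates 1 and 3 are the dim arrays, and replicate 2 correlated with R1 at 0.964 to 0.969 across probes. Without the dim arrays 2791 genes were called, with the 1 array left assumed to vary like the other groups. Lyz1 and Lyz2, lysozyme genes of macrophages and epithelia, were detected on no R1 array and were at least 41.5-fold and 13.1-fold higher in V6.5. Fos and Egr1, immediate early transcription factors, were at -3.42 ± 0.19 and -3.45 ± 0.25 in R1 relative to V6.5, the interferon-induced gene Usp18 was at least 8.61-fold lower, and Id1 was 2.15 ± 0.19 higher. Also lower in R1 were the matrix gene Dcn at -3.04 ± 0.22, the fibroblast gene Thy1 at -1.90 ± 0.18 (6.72 against 8.61 in V6.5) and the cell cycle inhibitor gene Cdkn2b, a TGF-beta target, at -3.18 ± 0.23. Pou5f1 was 4.18 ± 0.72 higher in R1, but V6.5 arrays spread with an SD of 2.95, 2 of 3 detected it, and without the dim arrays it was 0.84 (adjusted p = 0.0023). Without them Fos was at -3.18, Egr1 at -2.44, Dcn at -2.24 and Cdkn2b at -2.39, all still called. Interferon (7 of 11 lower and 1 higher, adjusted p = 0.016), immediate early (5 of 8 lower, 0.016) and macrophage genes (3 of 3 lower, 0.036) were called lower on either adjustment, and Nodal targets (3 of 5, 0.036) and Myc targets (8 of 14, 0.036) higher. The matrix list (8 of 23 lower and 4 higher on either adjustment, adjusted p = 0.19) and the fibroblast list (7 of 15 lower and 2 higher, 7 and 3 adjusted over the list alone, adjusted p = 0.27) were not called, and the labels do not say which of these cultures held fibroblast feeders. With an estimated correlation the adjusted p-values of the called lists were 0.082, 0.082, 0.17, 0.30 and 0.082. Without V6.5 replicate 2 they were 0.091, 0.16, 0.13, 0.091 and 0.16, and without replicate 1 the macrophage and Nodal calls were lost too (0.061 and 0.063). The macrophage call was also lost with no detection filter (0.065) and the Myc target call with a stricter one (0.091). Median scaling moved the median of all genes by 0.85 log2 and called 6586 genes higher and 983 lower, and with it the Nodal and Myc target calls were lost (adjusted p = 0.27 and 0.052). With only these 6 arrays in the model, 152 genes were called, and Pou5f1 was not among them (4.26, adjusted p = 0.12).

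Untreated OKMS6 cells had lower levels of most pluripotency genes than embryonic stem cells but higher Klf4 and Myc on the probes used. The line was virally transduced, and any viral RNA of such factors is not told apart here from that of the cells' own genes. Esrrb, Dppa4 and Dnmt3l, all embryonic stem cell genes, were detected on no OKMS6 array and were at least 90.2-fold, 123-fold and 109-fold lower than in embryonic stem cells (9 against 6 arrays). Nanog was at -7.36 ± 0.08 relative to embryonic stem cells, detected on 3 of 9 OKMS6 arrays, and Sox2 was at -2.33 ± 0.21, detected on 3 of 9 OKMS6 and 5 of 6 embryonic stem cell arrays. On that Sox2 probe R1 was at 7.82 and V6.5, with the dim arrays, at 6.30 (SD 1.23). On the other Sox2 probe R1 was at 7.99 and V6.5 at 8.13 (SD 0.35). Untreated OKMS6 cells were at 4.27, 4.30 and 4.29 on it at the 3 times, undetected, so the gap was wider there. Myc was detected on no embryonic stem cell array and was at least 15.8-fold higher in OKMS6 cells. Klf4 was 3.67 ± 0.33 higher, with 1 of its 2 other probes called in the opposite direction and a value of 2.49 without V6.5 replicates 1 and 3, and Pou5f1 was at 2.05 ± 0.46, detected on 4 of 6 and 5 of 6 embryonic stem cell arrays. That Pou5f1 value rests on V6.5 (7.45, SD 2.95), since R1 was at 11.62 ± 0.16 and untreated OKMS6 cells at 11.35, 11.59 and 11.83 at the 3 times. Without V6.5 replicates 1 and 3 it was 0.39 (adjusted p = 0.0044). Of 24 pluripotency genes 20 were lower and 3 higher (adjusted p = 1.5e-10), and 12 of 13 epithelial genes were lower (adjusted p = 4.0e-07), with Krt8 at -4.91 ± 0.13. Lower lists also included matrix (17 of 23 lower and 1 higher, adjusted p = 1.4e-05), endoderm (7 of 9, 0.0032), immediate early (7 of 8 lower and 1 higher, 0.0050), Nodal targets (4 of 5, 0.0077), TGF-beta targets (8 of 13 lower and 1 higher, 0.011), contractile (10 of 13 lower and 2 higher, 0.012), interferon (8 of 11, 0.012), skeletal muscle (4 of 6, 0.026) and germline genes (3 of 4, 0.043). Myc targets (11 of 14 higher and 2 lower, 12 and 2 adjusted over the list alone, adjusted p = 0.020) and endothelial genes (3 of 4, adjusted p = 0.026) were higher, with Srm at 2.38 ± 0.17 and Pecam1 at 2.57 ± 0.21. Member counts of the other lists did not move when adjusted over the list alone. The Nodal and germline calls were lost with an estimated correlation (adjusted p = 0.11 with an estimated correlation and adjusted p = 0.17 with an estimated correlation), the Myc target call with median scaling (adjusted p = 0.13), the endothelial call with the series matrix (adjusted p = 0.082) and the skeletal muscle call without V6.5 replicate 2 (adjusted p = 0.058). Of 7161 genes called, 3649 were higher and 3512 lower; median scaling moved the median of all genes by 0.29 log2 and called 5027 higher and 1966 lower.

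Against fibroblasts, untreated OKMS6 cells had lower matrix, fibroblast and contractile genes and higher cell cycle and Myc target genes. All 23 matrix genes were lower (adjusted p = 1.1e-18), with Lox at -7.60 ± 0.59, and the matrix calcification inhibitor gene Mgp was at least 376-fold lower (3 fibroblast against 9 OKMS6 arrays). All 15 fibroblast genes (adjusted p = 4.3e-09) and 12 of 13 contractile genes (adjusted p = 8.4e-09) were lower, with Thy1 at -4.70 ± 0.15 and Acta2 at -4.65 ± 0.10. All 16 cell cycle genes (adjusted p = 7.2e-07) and all 14 Myc targets (adjusted p = 3.0e-05) were higher, with Mcm5 at 3.41 ± 0.13 and the nucleolar gene Fbl at 2.16 ± 0.13. Pou5f1, the pluripotency gene Fbxo15 and Myc were detected on no fibroblast array and were at least 110-fold, 92.1-fold and 20.6-fold higher. For Pou5f1 and Myc, any viral RNA is not told apart from that of the cells' own genes. Interferon genes were lower (8 of 11, 9 adjusted over the list alone, adjusted p = 1.2e-04), as were immediate early genes (6 of 8 with 1 higher, 0.0034) and TGF-beta targets (8 of 13 with 1 higher, 0.0052). Chromatin regulators (7 of 10 with 1 lower, 0.013) and pluripotency genes (10 of 24 with 2 lower, 0.021) were called higher and endoderm genes (4 of 9, 0.047) lower, with adjusted p = 0.077, 0.12 and 0.15 with an estimated correlation. Member counts of the lists other than interferon did not move when adjusted over the list alone. The endoderm call was lost without untreated replicate 2 at 10 h or replicate 1 at 24 h (adjusted p = 0.0501 and 0.0502), and the pluripotency call with median scaling (adjusted p = 0.58). Of 6283 genes called, 3400 were higher and 2883 lower; median scaling moved the median of all genes by 0.42 log2 and called 5126 higher and 1586 lower.

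The iPS line stood nearer embryonic stem cells than fibroblasts for most genes that separate them, with platform and cell type confounded. Of 521 genes at least 4-fold higher in embryonic stem cells, 81.2% were nearer the embryonic stem cell mean (SD over the 3 arrays 1.39), and of 628 genes at least 4-fold higher in fibroblasts 79.3% were (SD 0.574). In untreated OKMS6 cells the shares were 46.5% to 49.6% and 73.3% to 75.4%. Nanog was at 12.28 ± 0.10 in the iPS line (SD, n = 3), 11.63 in R1, 12.31 in V6.5 and 4.51 in fibroblasts. Sox2 was at 8.14 ± 0.18 in the iPS line, 7.92 in R1 and 4.61 in fibroblasts, and Lefty1, a Nodal antagonist and target, was at 10.34 ± 0.22, 8.94 and 5.16. Pou5f1 and Zfp42, another embryonic stem cell gene, were at 9.77 ± 0.25 and 8.51 ± 0.06 in the iPS line against 11.71 and 10.82 in R1 and 7.55 and 7.49 in V6.5 (SD 2.93 and 2.26), which holds the dim arrays. Thy1 was at 8.77 ± 0.12 in the iPS line, 6.79 in R1, 8.64 in V6.5 and 11.64 in fibroblasts. Myc was detected on 1 of 3 iPS arrays (4.63 ± 0.15). Of 21 shared pluripotency genes 19 were nearer embryonic stem cells and 20 were detected on all 3 iPS arrays, and all 12 shared epithelial genes were nearer. Under 50% were nearer among cell stress (2 of 8), endoderm (3 of 9), p53 (4 of 10), cholesterol (4 of 10) and macrophage genes (1 of 3). The labels do not say which cultures grew on fibroblast feeders. Rank correlation across genes, which are not replicates, averaged 0.798 with R1, 0.692 with V6.5 (0.609 to 0.823), 0.688 with fibroblasts and 0.684, 0.695 and 0.708 with untreated OKMS6 cells at 10, 24 and 48 h. Group means other than that with R1 ran from 0.673 to 0.708. The V6.5 mean holds the dim arrays, replicates 1 and 3, which were at 0.609 to 0.646 with the iPS arrays. Replicate 2, the 1 V6.5 array that was not dim, was at 0.818 to 0.823, above every value with R1.

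**Figure D3:**
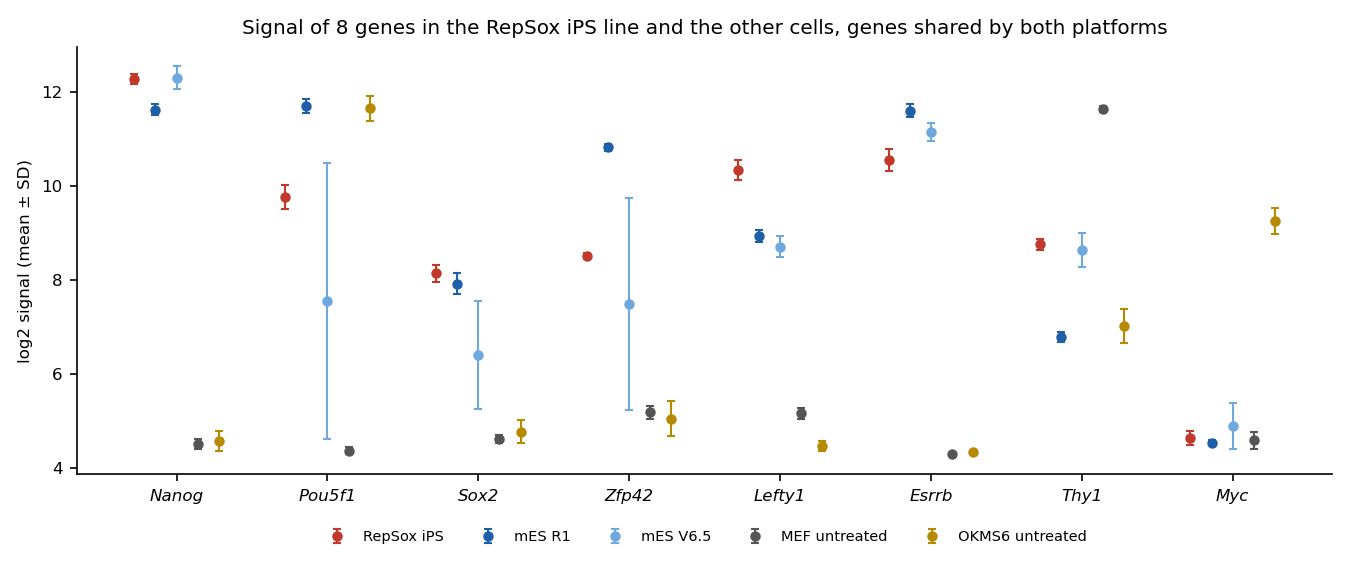
Log2 intensity of selected genes in the iPS line, R1, V6.5, fibroblasts and untreated OKMS6 cells after joint quantile normalization over 9495 shared genes, as means ± SD. Nanog was at 12.28 in the iPS line and 4.58 in untreated OKMS6 cells, and the iPS values come from another platform.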

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

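The tests on which deposited table holds exchanged names, on Nanog without the arrays concerned, on uniform dimming, on other groups' arrays under V6.5 titles and on splits within each cell type were chosen after the result was seen. The RepSox effect in OKMS6 cells differed between 10, 24 and 48 h for 934 genes by a test of the difference. It differed between fibroblasts at 1 week and OKMS6 cells at 48 h for 1699 genes, and those times differ.

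All differences here are between fitted log2 changes, and they are not exact where a group was undetected. Genes that moved in opposite directions included the contractile kinase gene Mylk, at 3.22 in fibroblasts and -2.67 in OKMS6 cells (difference 5.90), and the integrin gene Itga7, at 1.70 and -2.76 (difference 4.46), and neither was detected on a treated OKMS6 array (at least 4.79-fold and 5.85-fold lower). The ferritin receptor gene Scara5 was at 3.39 and -3.51 (difference 6.90, detected on 1 of 3 untreated fibroblast arrays) and the acute-phase gene Serpina3n at 0.60 and -4.40 (difference 5.003). Plac8 was at 0.45 (adjusted p = 0.0499 in fibroblasts) and -3.20 (difference 3.65). Rgs8, a regulator of G protein signalling, was at 0.83 and -2.81 (difference 3.64), detected on no untreated fibroblast array (at least 1.31-fold higher) and no treated OKMS6 array (at least 6.12-fold lower). The kininogen gene Kng1 was at -1.83 and 4.54 (difference -6.36), detected on no untreated OKMS6 array (at least 19.03-fold higher), and the glutamate transporter gene Slc17a6 at -1.14 and 3.26 (difference -4.40), detected on no treated fibroblast array (at least 1.98-fold lower). The effect also differed for Nanog (difference -2.95, adjusted p = 4.9e-12), which was detected on no fibroblast array. It differed for Mycl (2.13, adjusted p = 5.1e-07), Thy1 (1.55, adjusted p = 7.2e-05) and Myc (1.36, adjusted p = 0.0012), which was detected on 1 of 3 treated and no untreated fibroblast arrays.

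Nanog rose in OKMS6 cells at 48 h with RepSox, on 1 probe. The level would need 4.58% of embryonic stem cell RNA in the treated cultures. Of 31 genes undetected in untreated cells at 48 h and at least 16-fold higher in embryonic stem cells, 90.3% showed under 50% of that share and 77.4% were undetected on all treated arrays, which argues against such a share. Gpc3 (5.09%), Fhl1 (4.43%) and Nr5a2 (2.34%) showed 50% of it or more. Without both arrays numbered 3 Nanog was at 2.86 ± 0.16 (adjusted p = 1.4e-11), which argues against exchanged names as the cause, and a response to RepSox stays open as a hypothesis.

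The replicate 3 arrays of OKMS6 cells at 48 h carry each other's values in the scanner table and the series matrix. Of 974 genes called at 24 h, 78.4% went the 24 h way within pair 3 under the scanner names, against 78.0% and 78.1% in pairs 1 and 2. Under the series matrix names 19.7% did in pair 3, against 75.4% and 75.2%. The values argue against an exchange in the scanner table, and an exchange of names in the series matrix may be the source. No biological explanation was tested.

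V6.5 replicates 1 and 3 were dim and differed from replicate 2. Of 2142 bright probes, 18.9% and 27.3% lay more than 4-fold from the median ratio to replicate 2, 0.467% did so between replicates 1 and 3 and 0 between R1 arrays, which argues against uniform dimming. This measure was chosen after an earlier one, 3.22% of bright probes lost on both arrays, fell between its bounds. Of 31 lost probes with a second bright probe for the gene, 74.2% had that one detected (91.4% of 467 for kept probes), so failure of single probes may account for part of the losses. Across the 10614 genes, with 1 probe each, the highest mean correlation with a group other than V6.5 and R1 was 0.738, against 0.841 and 0.805 with replicate 2, which argues against arrays of another group, and no biological explanation was tested.

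Splits of 3 against 3 arrays number 10, too few for a share under 0.05. The real splits, each the 1 split to reach its count, called 412, 974 and 1695 genes for RepSox at 10, 24 and 48 h, 1608 in fibroblasts and 6219 between R1 and V6.5, and the highest other splits 0, 0, 0, 2 and 5235. At 48 h, where same-numbered arrays shared deviations, the other splits that part as many pairs also called 0. A chance division of these arrays can be excluded for OKMS6 cells against embryonic stem cells (7161, highest other 4747) and against fibroblasts (6283, 3192). The same holds for untreated cells between times (2125, 1526), and each had 100 splits. The splits divide arrays that may share a culture, so chance differences between cultures are not excluded. For the RepSox effect between times (934, highest other 796, 100 splits), time labels were exchanged separately among treated and among untreated arrays. Differences between times thus entered the contrast and the spread, and these splits cannot decide the question. For embryonic stem cells against fibroblasts 2 of 84 splits, the real one included, reached 6646, a share under 0.05. The highest other called 6916, more than the real groups, so the count does not single out the real grouping. No conclusion is drawn from it. For the difference between fibroblasts and OKMS6 cells, 10 of 100 splits that mix the cell types reached 1699, and the highest other called 4541. These splits are no reference for chance: the other 9 that reached it were the 9 whose treated and untreated arrays kept numbers of fibroblast arrays that differ by 2, so that cell types differ within the contrast. With arrays split only within each cell type, 2 of 100 splits reached 1699. The other of these called 2139, with all treated and untreated OKMS6 arrays exchanged. Splits that mixed treated and untreated arrays of a cell type called at most 746, which speaks only against a chance division of treated from untreated arrays. Such splits break up the RepSox effect itself, so they cannot show whether the effect differs between cell types. No conclusion on that difference is drawn from them.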

How the results depend on the processing

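The settings that leave out V6.5 replicates 1 and 3, or both 48 h arrays numbered 3, or match iPS genes by probe identifier, were chosen after the data were seen. Of 373 values of named genes, 344 were called, 201 of these kept direction and call in every setting, and the direction reversed in 12 cases. Over settings other than left-out arrays, named genes kept their direction and side of the threshold in 4215 cases, lost the call in 209 and gained one in 40, and called lists held in 641 cases and were lost in 62. With single arrays left out, named genes held in 2962 cases and lost the call in 106, and called lists held in 614 and were lost in 16. The cause of changes was not tested except where stated. Genes near the background have little range to fall, and dim arrays limit the V6.5 values.

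Requiring at least a 2-fold change, a stricter demand, left 73, 255 and 492 genes at 10, 24 and 48 h, 612 in fibroblasts, 3583 for embryonic stem cells against fibroblasts, 3023 for R1 against V6.5, 2648 and 3244 for OKMS6 cells against embryonic stem cells and fibroblasts, and 968 for the difference between cell types. Median scaling gave 256 at 10 h, 905 in fibroblasts and 495 for the effect between times. The series matrix gave 218, 614 and 0 (limma, with 187 at an unadjusted p under 0.05) at the 3 times, 57 for the effect between times, 1330 for untreated cells between times and 665 for the difference between cell types. With both 48 h arrays numbered 3 left out of the series matrix these were 445, 951, 1136, 650, 1549 and 1398, each within 1.5 times of the reported count. Array weights raised the same counts to 2782, 4904, 4608, 5347, 6623 and 4845, and fibroblasts to 4205. Fitting only the groups compared gave 1254, 1648, 3888, 2852, 5526 and 3444, each above the reported count, but 152 for R1 against V6.5. The spread then comes from the compared groups alone. V6.5 arrays spread widely (Pou5f1 SD 2.95, against 0.16 in R1), and the reported fit pools that spread over all groups. Reported SEs may thus be too small for comparisons with V6.5 and too large for those without it. Without V6.5 replicates 1 and 3 the counts were 1333, 2549, 3450, 2779, 4762 and 3530, with 3000 in fibroblasts and 2791 for R1 against V6.5. Without both 48 h arrays numbered 3 they were 1041 at 48 h and 539 for the effect between times.

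With the replicate number as a block, the effect between times was called for 620 genes, and the matrix list in fibroblasts lost its call (adjusted p = 0.054, over other settings 1.2e-05 to 0.28). It changed no other list call and moved no other count of genes called in a comparison by over 1.5 times. Among the values of named genes, 6 lost their call with it. Overlaps between comparisons stayed within 1.5 times in 83 cases and moved further in 61. Counts with single arrays left out ran from 229 to 296 at 10 h and from 629 to 1030 at 24 h. Chip was not used as a block because column names carry none.

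Against 64 list calls, there were 42 with an estimated correlation, and fry, which asks another question, called 151. The pluripotency call at 48 h was also lost without background correction (adjusted p = 0.077). The series matrix also ended the trophectoderm call at 10 h (adjusted p = 0.20), the macrophage call for R1 against V6.5 (0.083) and the endoderm call for OKMS6 cells against fibroblasts (0.086), which was lost without background correction too (0.0504). With both 48 h arrays numbered 3 left out of the series matrix, calls were also lost for macrophage genes between R1 and V6.5 (0.081), for Myc targets and chromatin regulators between embryonic stem cells and fibroblasts (0.0505 for each) and for germline genes between OKMS6 and embryonic stem cells (0.064). With that setting the 48 h call for genes higher in embryonic stem cells was lost (0.29). Of 3 calls for genes separating embryonic stem cells from fibroblasts, there were 0 with an estimated correlation, 5 with fry and 1 with lists of 100 genes.

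For the iPS line, the share of genes higher in embryonic stem cells that lay nearer them was 85.6% with ranks, 79.3% with genes detected on all iPS arrays, 71.0% and 84.6% at 2-fold and 8-fold, 78.5% with the mean of all probes, 85.3% with the same probe identifier and 82.7% without the dim V6.5 arrays. For genes higher in fibroblasts it was 70.2% with ranks, 77.4% with the series matrix, 80.7% with detected genes, 70.0% and 83.9% at 2-fold and 8-fold, 78.2% with the mean of probes, 84.2% with the same identifier and 86.2% without the dim arrays.

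Reversals were in Mcm6 (2.32 for embryonic stem cells against fibroblasts and 1.15 for R1 against V6.5, with only the groups compared) and Klf4 for embryonic stem cells against fibroblasts (-0.37 without V6.5 replicate 2 to 0.51 without replicate 3). For R1 against V6.5, Sox2 was at -0.14 with the series matrix, also without the 48 h pair, and -0.15 with only these groups. Klf4 was at -0.25 with only these groups and -0.36 without the dim arrays, and Id3 at 1.02 with median scaling and 0.38 without the dim arrays. With median scaling Nanog was at 0.25 there, and Thy1 at 0.0043 for OKMS6 cells against embryonic stem cells. The Sox2 values and the Klf4 value of -0.25 match a change of probe rather than of a probe's value. In R1 and V6.5 the reported Sox2 probe was at 7.82 and 6.30, and the other at 7.99 and 8.13. The reported Klf4 probe was at 7.44 and 5.44, and another at 8.19 and 8.43.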

Other observations

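All values here are descriptive, and the probe values of reprogramming factors were looked at after the main results were seen. Several lists were not called at 48 h in OKMS6 cells. Matrix genes fell and rose (5 and 2 of 23, adjusted p = 0.73), with the metalloproteinase inhibitor gene Timp3 at -1.60 ± 0.19 and Timp1 at -0.86 ± 0.13. Epithelial genes went both ways (1 of 13 rose and 2 fell, adjusted p = 0.82), with Cdh1 at 0.88 ± 0.19 and the keratin genes Krt8 at -1.37 ± 0.21 and Krt19 at -2.13 ± 0.42, detected on 1 of 3 treated arrays. Immediate early genes fell singly (3 of 8, adjusted p = 0.15), with Fos at -2.58 ± 0.19. Junb, of the TGF-beta target list, was at -1.01 ± 0.17. Nodal targets (0 of 5, adjusted p = 0.88), germline (0 of 4, 0.88), cholesterol (0 of 10, 0.88), interferon (0 of 11, 0.88), adipocyte (0 of 6, 0.88) and p53 genes (0 of 10, 0.96) had no called member. Mesoderm (1 of 4 fell, 0.76), neural (2 of 6 fell, 0.73), macrophage (1 of 3 fell, 0.39), endoderm (2 of 9 fell, 0.23), skeletal muscle (1 of 6 rose, 0.32), chromatin (1 of 10 rose, 0.73), trophectoderm (1 of 6 rose and 1 fell, 0.73) and Myc target genes (1 of 14 rose, 0.58) were not called as lists. These member counts did not change when adjusted over the list alone. The median and mean of the neural list differed in sign (0.10 and -0.30), as did those of the trophectoderm list (-0.07 and 0.20) and the macrophage list (0.02 and -0.33). For interferon and p53 genes the test leaned up while the means were -0.02 and -0.01.

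In fibroblasts after 1 week with RepSox, hypoxia and glycolysis genes were not called as a list (3 of 10 rose and 1 fell, adjusted p = 0.065), with Egln3 at 1.63 ± 0.22 and adrenomedullin (Adm) at 1.53 ± 0.19. Immediate early genes (2 of 8 rose and 1 fell, adjusted p = 0.12), Myc targets (2 of 14 fell, 0.53), cell cycle (1 of 16 rose and 1 fell, 0.86), pluripotency (1 of 24 fell, 0.98) and Nodal target genes (0 of 5, 0.86) were not called. The same held for epithelial (1 of 13 rose, 0.86), endothelial (1 of 4 rose and 1 fell, 0.98), neural (1 of 6 fell, 0.32), macrophage (1 of 3 fell, 0.13), skeletal muscle (2 of 6 rose, 0.44), trophectoderm (2 of 6 rose and 1 fell, 0.86), chromatin (1 of 10 fell, 0.98), mesoderm (0 of 4, 0.98), germline (0 of 4, 0.89) and cholesterol genes (0 of 10, 0.86). For p53 (1 of 10 fell, 0.42) and endoderm genes (1 of 9 fell, 0.98), 1 more rose when adjusted over the list alone, and counts of the other lists did not move. The endothelial list had a median of -0.06 and a mean of 0.24 and the epithelial list -0.04 and 0.07, and the mesoderm test leaned up with a mean of -0.08.

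Probes of the reprogramming factors differed, and whether viral RNA accounts for this was not tested. For Klf4, a pair of probes was at 10.19 ± 0.11 and 8.98 ± 0.22 in untreated OKMS6 cells at 48 h (SD, n = 3), against 7.44 and 6.42 in R1, while another was at 4.50 ± 0.13 and undetected in these cells, against 8.19 in R1 and 7.95 in fibroblasts. Both Pou5f1 probes were high in these OKMS6 cells (11.83 ± 0.25 and 10.79 ± 0.14). For Myc, 1 probe was at 9.10 ± 0.25 and the other at 4.27 ± 0.02, undetected in OKMS6 cells at 48 h, R1 and fibroblasts. For Sox2, which the labels name as viral in this line, both probes were low in OKMS6 cells at 48 h (4.58 ± 0.19, detected on 1 of 3 arrays, and 4.29 ± 0.06, detected on none) against 7.82 and 7.99 in R1.

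Some genes of the iPS line lay away from both R1 and fibroblasts. Nodal was at 9.75 ± 0.08 in the iPS line, 6.81 in R1 and 4.40 in fibroblasts, and Skil was detected on no iPS array (4.32 ± 0.03) against 9.71 in R1 and 9.44 in fibroblasts. The matrix genes Col3a1 and Dcn were at 7.75 ± 0.18 and 8.64 ± 0.23 in the iPS line, 4.69 and 4.98 in R1, 7.38 and 8.02 in V6.5, and 10.63 and 10.74 in fibroblasts. The labels do not say which cultures held fibroblast feeders, so RNA from feeders is not excluded for these matrix genes. The iPS values come from another platform with other probes for some genes.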
